A study of Bos taurus with 15 samples.

How the data were processed

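Total RNA from bovine testis collected at slaughter was measured on single-colour Agilent oligonucleotide arrays of 15 cattle, 7 untreated controls and 8 animals given prednisolone by mouth. Per the labels, the dose was 30 mg per head daily for 35 days. Each array held 1 animal, the groups shared no animal numbers, and the labels named no pairing.

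The deposited scanner files give each spot's brightness as intensity, and per the file headers they came from Feature Extraction 9.5.1.1. Per the series' design text, each slide was scanned at a high and a low sensitivity and the processed signal is background-subtracted and multiplicatively detrended. The intensity values of these files were not normalized between arrays. The authors also deposited a table of intensity values for the same 15 arrays. On 14 arrays its columns followed the processed signal of their own scanner file in rank, with Spearman correlations of at least 0.99998, and the blank spots were those the scanner software had not found. Its scale was linear, its column medians lay between 434.8 and 491.7, and it was not centred per gene. The method that brought its columns to a common level is not given in the sources used here, although the submitters' processing notes name R 2.11.1. For prednisolone 30, the deposited column did not come from the scanner file used here: the gene-centred values of file and column correlated at 0.0044, against 0.883 to 0.976 on the other 14 arrays. For this animal the scanner file and the deposited table are therefore different measurements, and which of them belongs to the animal was not settled.

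Spots of controls were left out, which left 42990 spots of 21475 probes. Spots marked as non-uniform or population outliers were masked and the spots of a probe averaged. The log2 processed signal was set relative to the 75th percentile of each array, so a level is a log2 distance from that percentile. A probe was tested when it was well above background on at least 7 of the 15 arrays in any group, which 18492 probes were. Probes were named through the accessions, gene numbers, symbols and descriptions in the scanner files and a table of bovine genes of assembly ARS-UCD2.0. Of the 21475 probes, 16947 had a gene symbol and 345 only a LOC number, a placeholder name. Among all of these, 3521 were named through an accession and 9882 through a gene number. The array's gene names are old, and the genome build of its design is not given in the sources used here, so no coordinates are given. A gene was read through its probe with the highest mean over all arrays.

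Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The adjustment ran over all tested probes, and a gene took the adjusted p of its probe. Gene lists with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry. List means were compared by an exact two-sided permutation test over the 6435 splits of 15 animals into 7 and 8, and 95% intervals of their difference came from inverting that test in steps of 0.005. A list mean is the mean over list genes of log2 values centred on each gene's mean over all arrays. The 31 gene lists, a panel of 16 genes, the tests and the naming rule were fixed before the data were examined. The rule took up to 12 genes per direction past the threshold, otherwise the 6 with the smallest unadjusted p in each direction, the panel genes, and for each list past the threshold the 4 members with the smallest unadjusted p. The value of 1 panel gene is not reported here.

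The fit was tested on simulated data of 13692 genes with the size of each array's noise kept and 200 genes changed per draw, in 20 draws. Each residual was given a random sign, which removed the correlation between genes, so the shares below do not cover data with such correlation. For the comparison of prednisolone with control on all arrays, 3.8% of genes changed by a log2 size of 0.5 were called, 47.7% at 1, 88.8% at 2 and 97.0% at 3, and 0.551% of calls were false. Without prednisolone 30 the shares were 10.4%, 70.7%, 97.7% and 99.7%, and 4.77% of calls were false. For lists, the arrays' residuals were regrouped at random in 20 draws. With no shift added, camera at the preset correlation called a mean of 6.5 of the lists other than the glucocorticoid list per draw, and at an estimated correlation 0. With the glucocorticoid list shifted by 0.5, camera at an estimated correlation called it in 14 of 20 draws and the permutation test in 12, and at a shift of 1 both called it in 20.

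The number of arrays limits the precision. Slide and scan day were read from the file headers. Slides 1 and 4 and scan day 1 held both groups, and every other slide and scan day held 1 group. Alternatives covered quantile and median scaling, normexp background correction with an offset of 50, the deposited table, the filter, slide and scan day as blocks, array weights, the variance prior and leaving out each animal. Further alternatives were added after seeing the data: leaving out control 17 and prednisolone 30 together, scan day 1, slide 1 and slide 4 alone, the deposited table without control 17, a covariate for spermatid against matrix genes, and list differences within scan day 1, slide 1 and slide 4 without control 17 and prednisolone 30.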

Results

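Gene expression was measured in testis tissue of 15 cattle, 7 untreated and 8 given the synthetic glucocorticoid prednisolone by mouth at 30 mg per head daily for 35 days. The comparison asked which transcripts in the testis differed between treated and control animals. On 14 arrays, between 82.2% and 89.9% of probes were well above background, and the 75th percentile of the processed signal lay between 1220 and 2780. The array of prednisolone 30 had 36.5% of probes well above background and a 75th percentile of 49.8. Its correlation with the other arrays was 0.749 to 0.779, against 0.949 to 0.993 among the other 14. Its scanner values also did not match its column in the authors' deposited table, so counts are given with and without it.

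**Figure D1:**
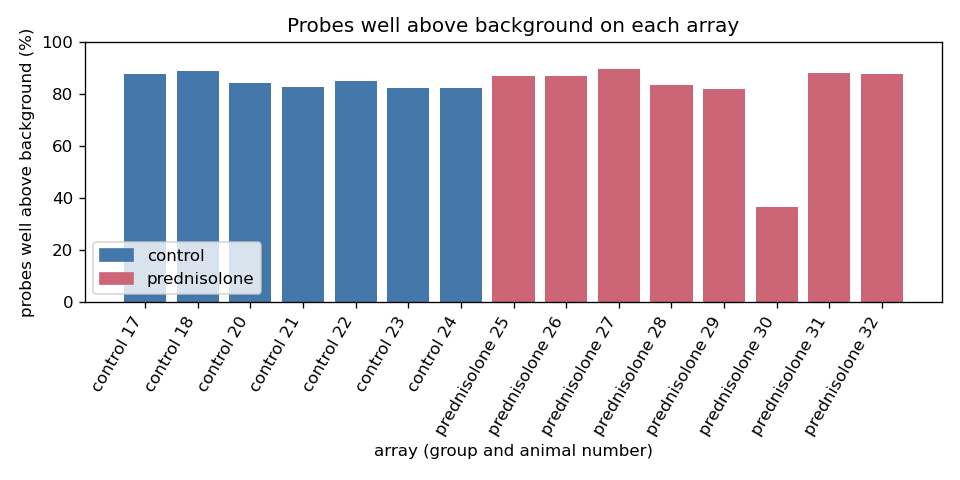
Percent of probes well above background (y axis) on each of the 15 arrays (x axis), with control animals in blue and prednisolone animals in red. Prednisolone 30 stands at 36.5%, and the other 14 arrays lie between 82.2% and 89.9%.

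No gene passed the threshold between prednisolone and control testis. Of 13694 genes tested with limma, 0 had an adjusted p under 0.05 and the smallest adjusted p was 0.883. At an unadjusted p under 0.05 there were 326 genes, or 2.38%, below the nominal 5%. Other random splits of the 15 arrays gave 83 to 2045 such genes, with a median of 281. Of 100 splits, the real one included, 43 gave at least as many. A count above or below the nominal 5% therefore says little by itself. Without prednisolone 30 the count past the threshold was 0 and 565 genes had an unadjusted p under 0.05. In the authors' deposited table it was 0 and 720, where the nominal 5% is 638, with a smallest adjusted p of 0.414. With array weights it was 0 and 853, where the nominal 5% is 684.7. The smallest adjusted p there was 0.109 among the probes that stand for genes and 0.0535 among all probes. With scan day as a block the counts were 0 and 232, with slide as a block 0 and 240, and within scan day 1 alone 0 and 112. Within slide 1 they were 0 and 475. Leaving out prednisolone 28 alone gave 0 genes past the threshold, with a smallest adjusted p of 0.225.

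The genes nearest to the threshold are given as values that did not pass. LRFN2, a synaptic adhesion protein, had the smallest unadjusted p. Its log2 level was -2.09 ± 0.43 (SD, n = 7) in controls and -2.94 ± 0.26 (SD, n = 8) with prednisolone, a difference of -0.84 with a 95% interval of -1.24 to -0.44. All 8 treated animals lay below the control mean, and the adjusted p from limma was 0.883. Its difference was -0.81 without prednisolone 30 and -0.84 in the deposited table. Among genes with lower values, CYFIP2, a regulator of actin assembly, differed by -1.58 ± 0.43 (SE). SLC50A1, a sugar transporter, differed by -1.44 ± 0.46 (SE). Its controls were split: controls 17, 18 and 22 lay at -2.68, -2.95 and -2.83, and the others between -0.58 and 0.02. Treated animals lay between -3.18 and -2.78, apart from prednisolone 30 at -1.74. RASD1, a small G protein, differed by -0.76 ± 0.23 (SE). IFI30, a lysosomal thiol reductase, differed by -0.59 ± 0.18 (SE), and SNX10, an endosomal sorting protein, by -0.46 ± 0.14 (SE). The probe of CYFIP2 used here and its other probe both had lower values, at -1.58 and -0.39.

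Among genes with higher values in treated animals, ZNF696 differed by 2.65 ± 0.73 (SE), but its probe was well above background on 2 of 7 control and 7 of 8 treated arrays. MCC differed by 1.55 ± 0.38 (SE) and was well above background on 3 of 7 control and 7 of 8 treated arrays. CSF3R, the receptor of granulocyte colony-stimulating factor, differed by 1.09 ± 0.30 (SE). PPP1R15A, a stress-induced phosphatase subunit, differed by 0.74 ± 0.21 (SE), SSPO by 0.72 ± 0.21 (SE) and MRGPRX2, a mast cell receptor, by 0.58 ± 0.15 (SE). In all 12 of these genes the adjusted p from limma was 0.883.

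The glucocorticoid response list, which holds genes known to be induced by cortisol-like steroids, showed no detectable shift. Of its 35 measured genes, 12 had higher and 23 lower values, and 0 passed adjusted over the list alone or over all tested probes. Its mean differed by -0.06, with a 95% interval of -0.28 to 0.145 (exact permutation p = 0.567). Without control 17 the difference was 0.01, without prednisolone 30 it was -0.09 and without both -0.02. With scan day as a block and within scan day 1 it was -0.09, with slide as a block -0.08, within slide 1 it was -0.28 and within slide 4 it was 0.28. Scan day 1 and slide 1 hold control 17, and scan day 1 and slide 4 hold prednisolone 30. Without these animals it was 0.08, 0.05 and 0.07 within scan day 1, slide 1 and slide 4, where 1 or 2 controls were left and no test was run. Steroid receptors and glucocorticoid metabolism differed by -0.04 (exact permutation p = 0.335).

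No gene of the panel of steroid response and testis genes passed. FKBP5, a chaperone strongly induced by glucocorticoids in many tissues, was 1.095 ± 0.51 (SD, n = 7) in controls and 0.99 ± 0.15 (SD, n = 8) with prednisolone. The difference was -0.10, with a 95% interval of -0.52 to 0.31. It was 0.08 without control 17, -0.15 without prednisolone 30 and 0.03 without both. PER1, a clock gene that glucocorticoids induce, differed by -0.03 (interval -0.49 to 0.43), and the glucocorticoid receptor gene NR3C1 by -0.22 (-0.84 to 0.40). The enzymes that regenerate and inactivate cortisol, HSD11B1 and HSD11B2, differed by 0.24 and 0.53. In the steroid synthesis path, STAR differed by -0.14, CYP11A1 by -0.08 and CYP17A1 by 0.25. Prednisolone 32 had the lowest value of all animals for each of these genes, at -0.25, -1.08 and 0.66. The next lowest animals lay at 1.34, -0.06 and 2.41. Prednisolone 32 thus pulled each difference down, and the negative signs of STAR and CYP11A1 may rest on it. The differences without prednisolone 32 are not given here. The Leydig cell hormone INSL3 differed by 0.26 and the luteinizing hormone receptor LHCGR by 0.33. AMH, a Sertoli cell hormone, was 0.42 ± 0.24 (SD, n = 7) in controls and 0.97 ± 0.56 (SD, n = 8) with prednisolone. Its difference was 0.55 (interval 0.07 to 1.03), 7 of 8 treated animals lay above the control mean, and it did not pass over the panel alone (limma adjusted p = 0.371). PRM1, the sperm chromatin protein, differed by 0.09. Of the 16 panel genes, 13 were tested and 0 passed adjusted over the panel alone. TSC22D3 was well above background on 0 of 7 control and 1 of 8 treated arrays and was not tested, and no probe was named HSD3B2 or HSD17B3. HSD11B1 was well above background on 5 of 7 control and 6 of 8 treated arrays. Leaving out prednisolone 30 turned the sign of PER1, HSD11B1 and CYP11A1, which differed by 0.14, -0.24 and 0.06 without it. It was not the only animal behind the CYP11A1 value, since prednisolone 32 lay lower, at -1.08 against -0.06. Without prednisolone 30, HSD11B2 differed by 0.18, NR3C1 by -0.02, INSL3 by 0.12, LHCGR by 0.21, PRM1 by 0.05 and AMH by 0.45. Without control 17, NR3C1 differed by -0.12 and STAR by -0.22.

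**Figure D2:**
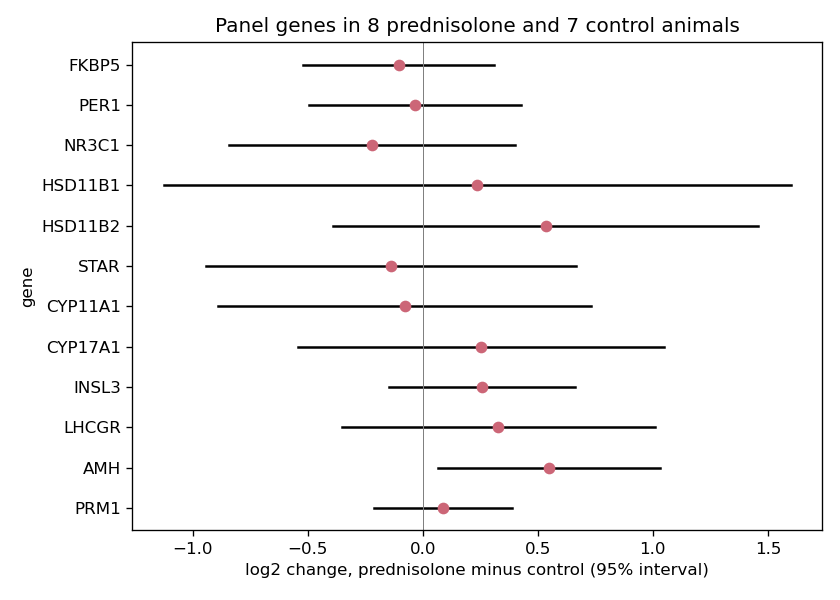
Log2 difference between 8 prednisolone and 7 control animals (x axis) for 12 panel genes (y axis), as points with 95% intervals from limma. Of the genes shown, the intervals of all but AMH include 0, and AMH lies at 0.55.

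Across the 31 gene lists, camera at the preset correlation called 3 lists, and none of these calls held with an estimated correlation, with fry or in the exact permutation test. The spermatid and sperm list had 39 of 48 measured genes with higher values in treated animals, and 0 passed adjusted over the list alone. Its mean was -0.08 ± 0.36 (SD, n = 7) in controls and 0.07 ± 0.22 (SD, n = 8) with prednisolone. The difference was 0.15, with an interval of -0.155 to 0.48 (camera adjusted p = 0.0195, adjusted p = 0.754 with an estimated correlation, exact permutation p = 0.363). TNP2, which packs sperm DNA, differed by 0.40, ODF1, of the sperm tail, by 0.45, GAPDHS, the sperm form of a glycolytic enzyme, by 0.59 and SPATA20 by 0.37. Without prednisolone 30 ODF1 differed by 0.25, and without control 17 TNP2 and SPATA20 differed by 0.27 and 0.18. In controls this list had its lowest mean, -0.80, in control 17, and without that animal the difference was 0.03. Without prednisolone 30 alone it was 0.19 (camera adjusted p = 2.98e-05, adjusted p = 0.985 with an estimated correlation, exact permutation p = 0.270). Without control 17 and prednisolone 30 it was 0.07, and the list was not called. In the deposited table it was 0.16 (camera adjusted p = 4.08e-07, adjusted p = 0.923 with an estimated correlation, exact permutation p = 0.0566), and there without control 17 it was 0.08 (camera adjusted p = 0.0107, adjusted p = 0.853 with an estimated correlation, exact permutation p = 0.137).

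The complement list had 20 of 23 genes with lower values. Its mean differed by -0.18, with an interval of -0.69 to 0.255 (camera adjusted p = 0.0367, adjusted p = 0.754 with an estimated correlation, exact permutation p = 0.584). CFI and CD59, which restrain complement, differed by -0.49 and -0.40 and C7 by -0.46, while the receptor C3AR1 differed by 0.74. Without prednisolone 30, C3AR1 differed by 0.23 and C7 by -0.28, and without control 17 CFI, CD59 and C7 differed by -0.26, -0.26 and -0.17. Ribosomal protein genes had 33 of 42 with lower values, and their mean differed by -0.13, with an interval of -0.395 to 0.095 (camera adjusted p = 0.00796, adjusted p = 0.754 with an estimated correlation, exact permutation p = 0.458). RPLP1 differed by -0.52, RPS12 by -0.40, RPS23 by -0.31 and RPS14 by -0.22. Without control 17, RPS12 and RPS23 differed by -0.27 and -0.19. Control 17 had the highest complement and ribosomal means of the controls, at 1.43 and 0.59, and prednisolone 30 the lowest ribosomal mean of the treated animals, at -0.65. The complement difference was 0.05 without control 17 alone, and the ribosomal difference -0.04 without either animal alone. Without these 2 animals the complement difference was 0.05 and the ribosomal difference 0.04, and neither list was called. Camera also called neither without prednisolone 30 alone (adjusted p = 0.148 and 0.249) or in the deposited table (adjusted p = 0.115 and 0.113). Without control 17 alone, camera called none of the 3 lists and instead called endothelium (adjusted p = 0.000277), meiosis and cell division (both 0.00458) and interferon response (0.00598). With an estimated correlation the adjusted p of these 4 was 0.764, and none passed in the permutation test.

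The 3 lists were also read within batches. With scan day as a block, the differences were 0.20 for spermatids, -0.36 for complement and -0.27 for ribosomal proteins, and within scan day 1 the same. With slide as a block they were 0.11, -0.27 and -0.27 (camera adjusted p = 0.279, 0.0279 and 1.78e-05), so the spermatid list was not called there. With slide as a block, 0 lists passed at an estimated correlation. Within slide 1 they were 0.38, -0.62 and -0.21, and within slide 4, with 1 control and 2 treated animals, they were -0.30, 0.25 and -0.35. Without control 17 and prednisolone 30, and with no test, the differences were -0.08, 0.24 and 0.05 within scan day 1, -0.04, 0.29 and 0.14 within slide 1, and -0.02, 0.28 and 0.02 within slide 4. These subsets hold 2 controls and 5 treated animals, 1 and 2, and 1 and 1. The other slides and scan days held 1 group.

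Over all 15 animals, besides spermatids no list of a testis cell type was called. Leydig cell and steroid synthesis genes differed by 0.12 (interval -0.145 to 0.385), Sertoli cell genes by -0.01 (-0.215 to 0.19), spermatogonial genes by 0.01 (-0.115 to 0.125) and meiotic genes by -0.06 (-0.27 to 0.17). Smooth muscle genes differed by -0.05, endothelial genes by 0.18 and matrix genes by -0.10. Genes of macrophages differed by -0.13, lymphocytes by 0.15, blood by 0.01, epididymis by 0.29 and adipocytes by 0.06. Single animals set many of these values. Leydig cell genes had their highest mean in prednisolone 30 (0.63) and their lowest in prednisolone 32 (-0.48), which pulled the difference in opposite directions. Without prednisolone 30, Leydig cell genes differed by 0.04, Sertoli cell genes by -0.0004, spermatogonial genes by -0.01, meiotic genes by -0.03, smooth muscle by -0.02, endothelial genes by 0.06, lymphocytes by -0.01, blood by -0.08, epididymis by 0.02 and adipocytes by -0.01. Without control 17, Sertoli cell genes differed by 0.03, meiotic genes by -0.14, smooth muscle by 0.14, endothelium by 0.31, matrix by 0.06, macrophages by 0.03, blood by -0.02 and epididymis by 0.46. Over all 15 animals, their exact permutation p lay between 0.385 and 0.973.

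**Figure D3:**
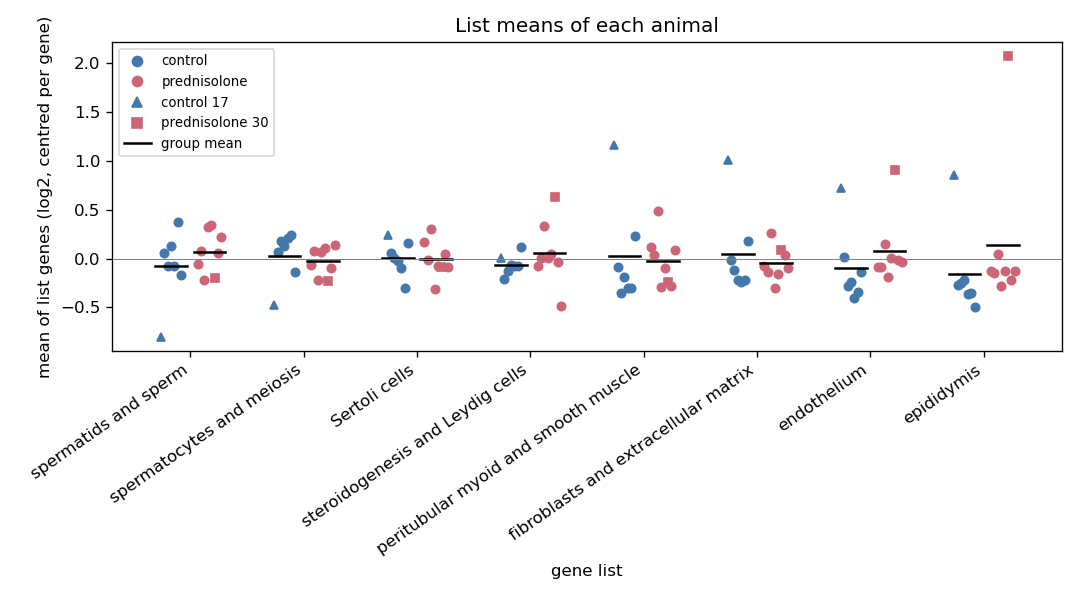
Mean of each gene list in each animal (y axis, log2, centred per gene) for 8 lists (x axis), with controls in blue, prednisolone animals in red and group means as black bars. Control 17 (triangle) lies at -0.80 for spermatids and 1.01 for matrix genes, and prednisolone 30 (square) at 2.07 for the epididymis list.

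Immune and metabolic lists also did not pass. Cytokines and NF-kB targets differed by 0.13, interferon response by 0.06 and antigen presentation by -0.21. Cholesterol synthesis differed by -0.10, drug metabolism by 0.03, insulin and IGF signalling by -0.11, oxidative stress defence by -0.07 and the mitochondrial respiratory chain by -0.04. Apoptosis differed by 0.08, cell division by -0.07, circadian clock by -0.04, immediate early genes by 0.05, heat shock by -0.08 and hypoxia by 0.05. Without prednisolone 30, cytokines differed by -0.04, interferon response by -0.02, cholesterol synthesis by -0.04, drug metabolism by -0.04, the respiratory chain by 0.02, apoptosis by 0.01, cell division by -0.02 and heat shock by -0.01. Without control 17, cytokines differed by 0.21, interferon response by 0.23, antigen presentation by -0.02, insulin and IGF signalling by -0.01, oxidative stress defence by -0.03, drug metabolism by 0.06, the respiratory chain by -0.07 and apoptosis by 0.12. Cell division differed by -0.12 there, circadian clock by 0.03, immediate early genes by 0.12 and hypoxia by 0.10. Over all 15 animals, their exact permutation p lay between 0.264 and 0.820.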

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

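The tests of array quality, slide, germ cell share, failed labelling, a swapped file and array noise were chosen after the results were seen. Each value below lay far from the other animals of its group by Dixon's ratio. Of 138 groups of values, 39 had such an animal, where chance gives about 6.9, and 13 were in control 17 and 19 in prednisolone 30.

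Control 17 stood above the other controls in the list means of smooth muscle (1.16), endothelium (0.72), matrix (1.01), interferon response (0.996), antigen presentation (1.23), complement (1.43), circadian clock (0.41), epididymis (0.86) and ribosomal proteins (0.59), and below them in cell division (-0.28). Its log2 levels of FKBP5 (2.18), CFI (0.85) and RPS12 (6.55) were also above. Poor array quality is argued against by its 87.7% of probes well above background, inside the 82.2% to 89.9% of the 13 other working arrays, and slide 1 by a mean spermatid list mean of 0.0245 on its 3 slide mates, inside the range of other slides. Fat and blood in the tissue piece are argued against by list means of -0.0339 and -0.17, inside the range of those 13 arrays, and a smaller share of germ cells alone by a gap of 1.01 between matrix and Leydig lists, against at most 0.39 on them. Epididymis or adjoining duct tissue in the piece may have contributed, since the epididymis list mean of 0.86 was above the 0.0451 that was the highest of those 13 arrays, although prednisolone 30 had 2.07. Of its 7 measured genes, out of 27 fixed, only PAX8, RNASE10 and NPC2 were higher in control 17 than on all of these 13 arrays, by 4.30, 2.45 and 1.39 over their mean, while CES5A and CST11 lay 1.04 and 0.49 below it, so this stays open. No other biological explanation was tested.

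Prednisolone 30 had 36.5% of probes well above background. Its list means were high for endothelium (0.90), lymphocytes (1.22), cytokines (1.23), drug metabolism (0.49), epididymis (2.07) and adipocytes (0.54), and low for cell division (-0.37), heat shock (-0.55), ribosomal proteins (-0.65) and the respiratory chain (-0.45). Its levels of SLC50A1 (-1.74), FKBP5 (1.32), HSD11B2 (-1.64), ODF1 (7.23) and C3AR1 (0.72) were high and those of PER1 (2.28), NR3C1 (-2.66) and RPS14 (5.60) low. Failed labelling or hybridisation is a candidate explanation: its spike-in signals correlated with the median array at 0.935, below the 0.998 of the lowest other array. The columns of the 14 other animals followed their own files, with Spearman correlations of at least 0.99998, so this is not the file behind any of them. Whether it is another array of one of these animals stays open: its highest correlation with any column of the deposited table was 0.0661, but an array that failed would be low with every column. Leaving it out raised the number of probes at an unadjusted p under 0.05 by 1.78 times, so its noise may account for part of the low count.

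Single values elsewhere were ZNF696 in control 23 (-4.70) and prednisolone 28 (-8.84), HSD11B1 in control 21 (-8.77), CYP11A1 in control 24 (1.80) and CYP17A1 in prednisolone 32 (0.66). Prednisolone 32 was also the lowest animal for STAR (-0.25), CYP11A1 (-1.08) and the Leydig cell list mean (-0.48), which Dixon's ratio did not flag. The spermatogonial list mean was -0.28 in prednisolone 28 and the oxidative stress list mean 0.19 in prednisolone 27.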

How the results depend on the processing

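Scan day 1, slide 1 and slide 4 alone, the spermatid covariate and the runs without control 17 or prednisolone 30 together with another change were added after seeing the data. No gene passed the threshold in any of 33 alternatives, which include all probes and an adjusted p under 0.1, and no panel gene (31 alternatives) or permuted list mean (26) did. Slide 4 is not counted: its 1 control was assumed to vary like its 2 treated animals, 1 of them prednisolone 30, and its 0 genes and lists say little at a median standard error of 1.60. For list means, slide 1 and slide as a block are not counted either, since their 6 and 18 splits give no permutation p under 0.0556, nor are scan day 1 and scan day as a block, where 84 splits give none under 0.0119 and 8 of the 31 lists would have to reach that to pass. The camera count of 3 lists was 1 with median scaling and in the deposited table, 5 with probes above background on all arrays, 8 with scan day as a block, and 0 with an estimated correlation and with fry. Leaving out 1 animal gave 1 to 7 lists: 1 without prednisolone 28, 29, 30 or 32 or control 24, 4 without control 17 (none of the 3), 5 without control 18, 6 without control 23 and 7 without prednisolone 27. It was 5 without control 17 and prednisolone 30, 8 on scan day 1, 10 on slide 1, 0 on slide 4, 6 in the deposited table without control 17 and 5 with the covariate. The cause was not tested. 15 camera directions turned where a call was made in either setting. Without control 17 and prednisolone 30, in the deposited table without control 17 and with the covariate, in this order, smooth muscle differed by 0.17, 0.18 and 0.18, complement by 0.0544, 0.0453 and 0.0508, and ribosomal proteins by 0.0436, 0.0483 and 0.0207. Without control 17 alone the complement difference was 0.0462, while its camera direction stayed lower. Slide 1 turned meiosis (0.21), endothelium (-0.45) and interferon (-0.33). Slide 4 turned spermatids (-0.30) and complement (0.25). Array weights turned the camera direction of ribosomal proteins (unweighted difference -0.13). Where nothing was called in either setting, a change of sign was not counted as a turn: 71 single-gene values, 137 camera directions and 155 list means had one. Prednisolone 30 had signal well above background on 36.5% of probes.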

Other observations

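The count of genes over other splits and the relation between lists were chosen after the results were seen. The direction of spermatid and matrix genes was opposed across animals. Over the 14 arrays other than prednisolone 30, the matrix list mean and the spermatid list mean correlated at r = -0.890 (permutation p = 0.00025) and rho = -0.705 (permutation p = 0.00647). This was the 1 relation tested. Without control 17 and prednisolone 27, the 2 animals farthest from the median on the matrix list, r was -0.576 (permutation p = 0.0488). Within scan day 1, over 8 arrays, r was -0.955 (exact permutation p = 0.00394) and rho -0.881 (exact permutation p = 0.00724), and r was -0.729 there without control 17. The other scan days held at most 2 arrays each. This relation was noticed and tested on the same data.

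A hypothesis was that this spread hid an effect of treatment. With the spermatid minus matrix list mean as a covariate and without prednisolone 30, 0 genes passed the threshold in limma, fewer than the 10 set beforehand. Against the fit without the covariate on the same arrays, genes at an unadjusted p under 0.05 went from 565 to 993, where the nominal 5% is 684.7. The smallest adjusted p went from 0.980 to 0.663. The camera lists at the preset correlation went from 1 to 5, and with the covariate 0 lists passed at an estimated correlation or in the permutation test. The prediction of at least 10 genes was thus not met, but this cannot exclude a hidden effect. In the simulation without prednisolone 30, which had no covariate, 10.4% of genes changed by a log2 size of 0.5 were called, a share that may be too low. The covariate was also built from genes of the same comparison, so it could take up a treatment effect on them.

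Chance cannot be excluded for the list count. For genes the real count of 0 fixes the outcome: all 100 splits of the 15 arrays give at least as many, so this says nothing, and the highest of the others was 0. For lists, 68 of 100 splits gave at least the 3 lists of the real groups, with 18 the highest of the others and a median of 5. The high counts may come from a structure of the samples or from correlation between the genes of a list. Random regrouping of residuals gave a mean of 6.5 lists at the preset correlation of 0.01 and 0 at an estimated correlation. Over all 15 animals the estimated correlation was 0.435 for spermatids, 0.305 for complement and 0.440 for ribosomal proteins. The preset value was thus too low for these lists. Structure of the samples and correlation between genes were not told apart.

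Without control 17 and prednisolone 30, a choice made after seeing the data, endothelial genes differed by 0.20 (camera adjusted p = 0.000347, adjusted p = 0.505 with an estimated correlation, exact permutation p = 0.0221, adjusted 0.343) and the epididymis list by 0.19 (exact permutation p = 0.00583, adjusted 0.181). In the deposited table without control 17 the same lists differed by 0.18 (exact permutation p = 0.00699, adjusted 0.108) and 0.13 (exact permutation p = 0.00266, adjusted 0.0826). None passed adjustment over the 31 lists in the permutation test. The 2 settings share all animals but prednisolone 30. Slides 2 and 3 held only controls, 20, 21, 22 and 24, with endothelial list means between -0.40 and -0.14. On slide 1 control 18 lay at 0.02, above prednisolone 25 and 26 at -0.09 and -0.08. On slide 4 control 23 lay at -0.34, below prednisolone 29 at 0.01. Treatment and slide cannot be told apart for most of these controls.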
